A study of Drosophila melanogaster with 9 samples.

How the data were processed

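Gene expression was measured in Drosophila S2 cells, a macrophage-like line derived from embryonic hemocytes, on 9 single-channel Affymetrix Drosophila Genome 2.0 arrays. The 9 arrays form 3 groups of 3: untreated cells, cells given double-stranded RNA (dsRNA) against the bacterial gene LacZ, which S2 cells lack, and cells given dsRNA against NELF, the negative elongation factor that holds RNA polymerase II near promoters. Per the labels' protocols, dsRNA was left on the cells for 72 h, the medium held 10% serum, 1 µg of total RNA was amplified and biotin-labelled with a 3′ kit, and 10 µg of cRNA was hybridized for 16 h. Scanning used GeneChip Operating Software 1.2.0.037, and Rosetta Resolver 6.0 is named in the series' design text. The groups were taken from the sample labels. Nothing in the labels says that the replicates of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. No scan dates were used here, so no batch could be tested.

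The deposited table gives 1 log2 intensity per probe set and array, as the authors processed it. The log2 scale was inferred from the values, which run from -16.3 to 13.6: from the median of all values to the highest lie 8.98 units, a 505-fold span if the base is 2 and 7938-fold if the values were natural logs. The summarization of probes into probe sets and the normalization between arrays are not given in the sources used here. Of 161091 cells outside the control probe sets, 34179 (21.2%) were empty, mostly on dim probe sets, and were kept as missing. Measured probe sets per array ranged from 13854 on NELF dsRNA array 3 and 13935 on LacZ dsRNA array 1 to 14196 on LacZ dsRNA array 3. Array medians over the 9266 probe sets measured on all 9 arrays lay within 0.025 of each other. This is under the bound of 0.1, fixed beforehand, above which arrays would be quantile normalized, so no further normalization was applied. Medians over whatever each array measured differed by 0.18, above that bound, because the number of empty cells differs. The rule did not say which of these medians to use. The number of arrays limits the precision.

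Probe sets were named through the platform annotation supplied for this series, with symbols checked through gene identifiers against a RefSeq gene table. Of 17899 probe sets other than controls, 13086 had 1 gene, 389 had several and 4424 were unnamed here. The identifiers of 12988 of the named ones matched the gene table. No gene was named from a probe set with several genes, and Nelf-A had no probe set of its own among the named ones and was not analysed here. No coordinates are given, since no genome build was used here.

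Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with 1 mean per group and the spread estimated from all 9 arrays. The 3 pairwise comparisons came from that model. A further comparison set the NELF dsRNA arrays against all 6 control arrays in a model with 2 groups. A probe set was tested where each of the 2 groups compared had at least 2 values, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05. The 95th percentile of the values of the 95 control probe sets, 3.77 on the log2 scale, served as a detection limit. Where all arrays of a group lay below it, the change is given as at least N-fold, with the dim group set at that limit. The same bound was given, a choice made after seeing the data, where a group mean lay below the limit. There it bounds the difference of the group means only, and arrays of the dim group above the limit differ by less. Where a gene had several probe sets, the one with the highest mean stood for it.

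The genes named were chosen by a rule fixed before the data were examined. Among genes past the threshold whose arrays did not overlap between the groups, with at least 1 group mean above the median of all tested probe sets (5.50), it takes the 12 largest rises and 12 largest falls of NELF dsRNA against LacZ dsRNA and the 5 largest each way of the other pairwise comparisons. It adds the NELF complex, reference genes and, from each gene list, up to 4 members with the smallest adjusted p in NELF dsRNA against LacZ dsRNA and up to 2 in LacZ dsRNA against untreated. Chance alone gives no overlap in 10% of comparisons of 3 arrays with 3. The 30 gene lists, fixed at the same time, covered transcription elongation, heat shock, immunity, hemocyte classes, signalling, metabolism, cell cycle, protein handling and markers of other tissues, and 29 had a tested gene. Prosap, which matched the proteasome pattern by spelling only, was taken out. The list of replication-dependent histones had no measured gene. Lists with at least 5 genes measured on all 9 arrays (25 lists, within 7099 genes) were tested with limma's camera at its preset correlation of 0.01, and again with a correlation estimated from the arrays. After the results had been seen, 3 further lists were written (lysosomal hydrolases and transporters, DNA damage response and repair, and glutathione synthesis and oxidative stress defence), and their camera p-values were adjusted over the 3.

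The test was run on simulated data for NELF dsRNA against LacZ dsRNA, with the 12975 probe sets, spread and empty cells of the real comparison and 200 changed probe sets in each of 5 draws. It recovered 39.4% of the 1.5-fold changes, 44.5% of the 2-fold and 57.3% of the 4-fold. In the brighter part of the probe sets (above their median), these shares were 72.1%, 97.3% and 100%. False calls made up 7.30% of the calls, above the nominal level. No call was made in a single further draw where nothing was changed. The spread used was that of the eBayes step, which draws the spreads of probe sets towards the trend. It therefore differs less between probe sets than the unadjusted spread. In simulated lists of 20 genes, camera called 100% of those shifted by 0.3 and 2.5% of those not shifted, at p under 0.05. The genes were simulated as independent. These shares therefore do not carry over to lists whose genes vary together, such as the antimicrobial peptides (estimated correlation 0.49).

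Alternatives fixed before the data were examined were a floor at the 10th percentile, an offset at the 25th percentile, quantile normalization, median scaling, the brighter probe sets only, no variance trend, 1 probe set per gene, an added fold threshold of 1.5, the replicate number as a block, only the 6 arrays compared and each array left out in turn. For gene lists they were the estimated correlation, the mean over all probe sets of a gene, the block and quantile normalization. Chosen after seeing the data were leaving out the 2 arrays with the fewest measured probe sets, LacZ dsRNA array 1 and NELF dsRNA array 3, and keeping only probe sets measured on all 9 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.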

Results

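Transcript levels were compared between 3 untreated samples of S2 cells, 3 treated with dsRNA against LacZ and 3 treated with dsRNA against NELF, each on its own array. LacZ dsRNA stands for the effect of adding dsRNA as such, and the comparisons ask which messenger RNAs change when the pausing factor NELF is depleted. The limit above which a probe set counts as detected was 3.77 on the log2 scale, and between 8010 and 8059 probe sets per array lay above it. Correlation coefficients between arrays of 1 group, over the 9266 probe sets measured on all 9 arrays, ran from 0.955 to 0.971, and between groups from 0.943 to 0.967.

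The genes targeted by the NELF dsRNA fell. NELF-B, a subunit of the complex, averaged 7.50 ± 0.11 (log2 intensity, SD, n = 3) after LacZ dsRNA and 4.71 ± 0.15 (SD, n = 3) after NELF dsRNA, a 6.92-fold decrease (log2 change -2.79, SE 0.15, limma adjusted p = 2.97e-08). Nelf-E, the RNA-binding subunit, averaged 7.75 ± 0.25 (SD, n = 3) and 3.33 ± 0.70 (SD, n = 3), with 1 of the 3 NELF dsRNA arrays above the detection limit. Its NELF dsRNA mean lay below that limit, so it was at least 15.8-fold lower (limma adjusted p = 8.93e-08; fitted log2 change -4.42, SE 0.26). Against untreated cells NELF-B fell by 2.53 on the log2 scale and Nelf-E was at least 17.1-fold lower. TH1, the Drosophila NELF-D subunit, averaged 8.15 after LacZ dsRNA and 8.10 after NELF dsRNA, and this difference did not pass (log2 change -0.05, SE 0.10, limma adjusted p = 0.88). LacZ dsRNA and untreated cells did not differ past the threshold in NELF-B (adjusted p = 0.58), Nelf-E (adjusted p = 0.92) or TH1 (adjusted p = 0.74).

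**Figure D1:**
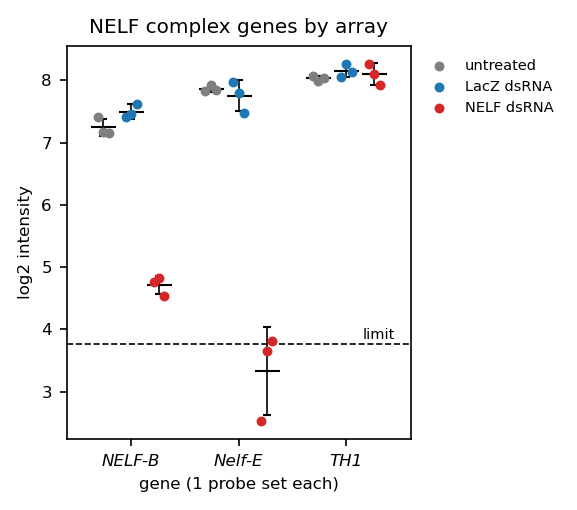
Log2 intensity of NELF-B, Nelf-E and TH1 (1 point per array; black bars are the group mean ± SD, n = 3; the dashed line is the detection limit of 3.77). NELF-B averages 4.71 and Nelf-E 3.33 after NELF dsRNA, against 7.50 and 7.75 after LacZ dsRNA, while TH1 averages 8.10 and 8.15.

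NELF dsRNA against LacZ dsRNA changed genes in both directions, with the larger changes mostly falls. Among the 12 rises chosen by size from the brighter genes, bbg, which encodes a PDZ-domain protein, was at least 6.50-fold higher by group means (fitted log2 change 2.84, SE 0.38). The LacZ dsRNA mean lay below the detection limit, but 2 of the 3 LacZ dsRNA arrays lay above it. Against those 2 arrays the rise was smaller than the bound. Act79B, a muscle actin, rose 3.63-fold, net, a basic helix-loop-helix repressor, 2.89-fold, Pepck1, a gluconeogenic enzyme, 2.87-fold, the odorant-binding protein gene Obp44a 2.77-fold and the glutathione S-transferase gene GstD5 2.68-fold. The gene oaf, which encodes a secreted protein, rose 2.57-fold (log2 change 1.36, SE 0.09), and its other probe sets rose by 1.97 and 1.56 on the log2 scale. CG9008, CG2247, CG14443, CG12868 and CG42788 complete the 12 rises, at 3.92-fold, 3.04-fold, 2.58-fold, 2.38-fold and 2.27-fold.

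Beside the targeted genes, the falls chosen by size included eater, a phagocytosis receptor of hemocytes, at 6.31-fold (log2 change -2.66, SE 0.40, 2 of 3 NELF dsRNA arrays above the limit). Sfxn1-3, a sideroflexin of the mitochondrial membrane, was at least 5.03-fold lower, with values on 2 NELF dsRNA arrays, 1 of them above the limit and their mean below it. The gene kon, a transmembrane proteoglycan of muscle attachment, fell 4.69-fold with 1 of 3 above it. CG44251 had values on 2 NELF dsRNA arrays, both below the limit, and was at least 4.73-fold lower (limma adjusted p = 0.00034), but its other probe set changed by -0.56 (log2, adjusted p = 0.53) and did not pass. By group means CG18557 was at least 4.48-fold and CG6163 at least 4.12-fold lower, with 2 of 3 NELF dsRNA arrays above the limit. On those 2 arrays the fall was smaller than the bound. CG8547 was lower with 1 of 3 above the limit. Each of these genes had its NELF dsRNA mean below the limit. CG46491 fell by 2.32 on the log2 scale, CG5399 4.69-fold and HisT 4.48-fold with all 3 above it.

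**Figure D2:**
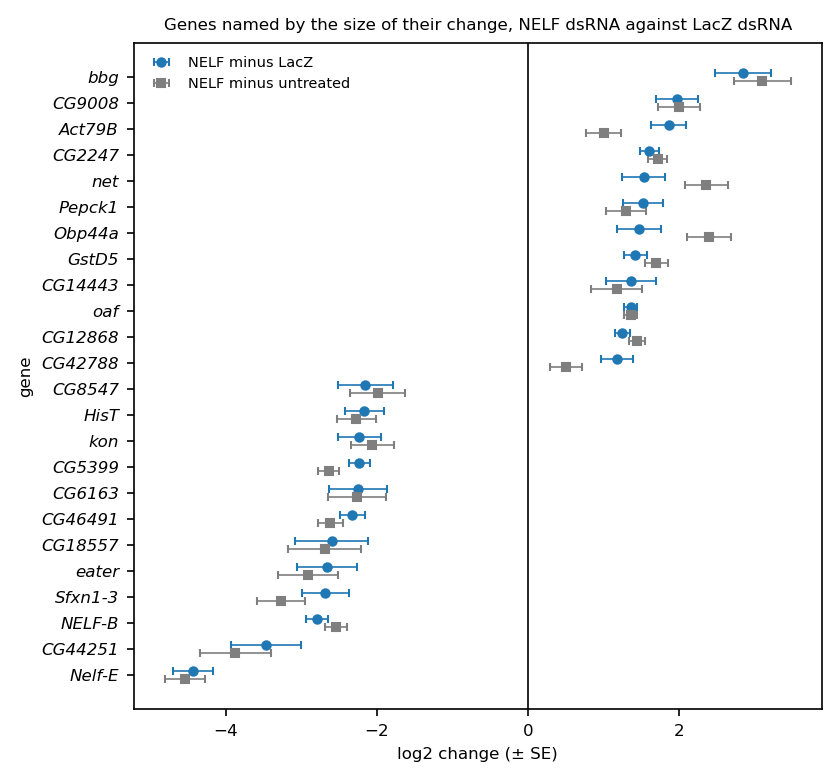
Log2 change (± SE, from the limma model) of the 12 rises and 12 falls chosen by size from the brighter genes in NELF dsRNA against LacZ dsRNA (circles), with the change against untreated cells (squares). For each gene both fitted changes have the same sign, from -4.42 and -4.54 for Nelf-E to 2.84 and 3.10 for bbg, and those of bbg, Nelf-E, Sfxn1-3, CG44251, CG18557, CG6163 and CG8547, and against untreated cells also net and Obp44a, rest on a group mean below the detection limit.

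In all, 592 of 12975 probe sets passed the limma test in NELF dsRNA against LacZ dsRNA, 240 higher and 352 lower. With a change of at least 1.5-fold as well, 91 were higher and 234 lower. Without the variance trend 228 probe sets passed, and among the named genes the calls of eater, CG44251, CG18557, CG6163, CG8547, Pepck1, CG14443, CG42788, drpr, Itgbn, ItgaPS4, Nplp2, br, Eip63E, Hph, bnl, eIF6, Prosalpha6, SdhB, Ssrp, glu, scra, aurB, RPA1, CycE, cher, SPARC, schlank and Sgt were lost. A floor at the 10th percentile ended the calls of eater, CG18557, CG6163, CG8547, Pepck1, CG14443, CG42788, drpr, Itgbn, ItgaPS4, br, Eip63E, Hph, bnl, glu, aurB, RPA1, CycE, cher and SPARC. Those of CG14443, Eip63E, Hph, bnl and Ssrp were lost without any of several single arrays, and that of ItgaPS4 without LacZ dsRNA array 3. CG14443 (adjusted p = 0.055) and CG42788 (adjusted p = 0.22) did not pass against untreated cells. The other tested probe sets of bnl, CG14443, Mmp2 and Tl, with means below the detection limit in both groups, did not pass.

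Some genes of the immune response fell after NELF dsRNA. Of 5 tested antimicrobial peptide genes 2 fell and 3 did not pass, and the list as a whole stood lower than other genes (camera adjusted p = 0.0033; adjusted p = 0.46 with an estimated correlation). CecB, a cecropin, fell 2.17-fold (log2 change -1.12, SE 0.14) and DptB, a diptericin, 2.31-fold (log2 change -1.21, SE 0.18), while Drs and AttD had values of -0.55 and -0.37 that did not pass. Adjusted over the list alone, 4 fell. Of 22 genes of immune recognition and signalling 2 fell, pirk, an inhibitor of the Imd pathway, 1.98-fold (log2 change -0.99, SE 0.12) and the receptor gene Tl 1.95-fold (log2 change -0.96, SE 0.13), and 3 fell adjusted over the list alone. The list did not pass camera (adjusted p = 0.20). Without LacZ dsRNA array 1 and NELF dsRNA array 3, which had the fewest measured probe sets, the median log2 change of the antimicrobial peptide list moved from -0.55 to -0.28 and its mean from -0.69 to -0.54, and 2 of its genes still fell. Camera then called 3 lists, with glycolysis and hypoxia lower (adjusted p = 0.042) and proteasome subunits higher (adjusted p = 0.020) besides this one. None of the 3 passed there with an estimated correlation (adjusted p = 0.82 with an estimated correlation for glycolysis and for proteasome, and adjusted p = 0.57 with an estimated correlation for antimicrobial peptides). Without those 2 arrays neither glycolysis nor proteasome passed camera in NELF dsRNA against untreated cells (adjusted p = 0.92 and 0.70). Camera without those 2 arrays called glycolysis higher (adjusted p = 0.0047) and proteasome lower (adjusted p = 0.019) in LacZ dsRNA against untreated cells. Both of those calls were lost with an estimated correlation (adjusted p = 0.81 with an estimated correlation for each). With all arrays kept, neither list passed camera in that comparison (adjusted p = 0.13 for glycolysis and 0.094 for proteasome).

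Markers of hemocytes moved both ways. Of 19 tested plasmatocyte markers 2 rose and 4 fell (3 and 4 adjusted over the list alone): beside eater, the engulfment receptor gene drpr fell 2.22-fold (log2 change -1.15, SE 0.18), while Pxn, an extracellular matrix peroxidase, rose 1.85-fold (log2 change 0.88, SE 0.11) and Nplp2 rose 1.32-fold (log2 change 0.40, SE 0.06). Of 11 crystal cell and lamellocyte markers 2 fell, the integrin genes Itgbn (log2 change -1.51, SE 0.30) and ItgaPS4 (log2 change -1.64, SE 0.36), each with 2 of 3 NELF dsRNA arrays above the limit, and 1 rose, cher, which encodes filamin (log2 change 0.38, SE 0.10). The counts adjusted over that list alone were the same. Against untreated cells Pxn (adjusted p = 0.18) and cher (adjusted p = 0.074) did not pass. Neither list passed camera (adjusted p = 0.91 and 0.46).

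**Figure D3:**
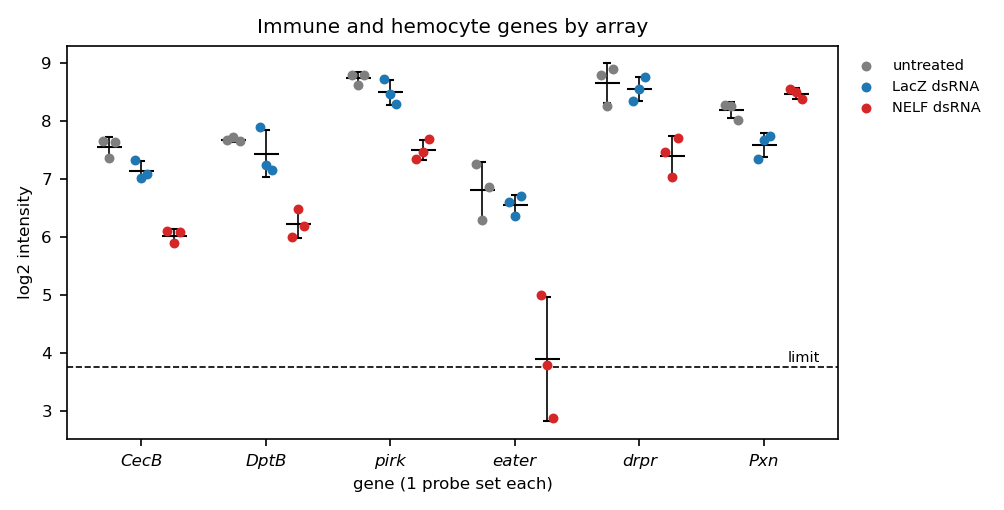
Log2 intensity of CecB, DptB, pirk, eater, drpr and Pxn (1 point per array; black bars are the group mean ± SD, n = 3; the dashed line is the detection limit of 3.77). The first 5 are lower on every NELF dsRNA array than on any LacZ dsRNA array, with log2 changes from -0.99 for pirk to -2.66 for eater, and Pxn is higher by 0.88.

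In the list of basement membrane and extracellular matrix genes 2 of 18 tested rose and 2 fell (3 and 4 adjusted over the list alone). Timp, an inhibitor of matrix metalloproteinases, had values on 2 LacZ dsRNA arrays, both below the limit, and was at least 1.78-fold higher after NELF dsRNA (limma adjusted p = 0.0081). It did not pass against untreated cells (adjusted p = 0.19), where its other probe set did (adjusted p = 0.022), and Pxn rose as given above. Mmp2, a matrix metalloproteinase, fell 3.22-fold (log2 change -1.69, SE 0.22), and SPARC, a collagen-binding protein, fell by 0.20 on the log2 scale (SE 0.05). Actin cytoskeleton and adhesion genes had 1 rise among 19 tested, cher again, with the same count over the list alone. Neither list passed camera (adjusted p = 0.98 and 0.43).

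Enzymes of detoxification changed in both directions, 8 of 80 tested glutathione S-transferase and cytochrome P450 genes rising and 11 falling (10 and 15 adjusted over the list alone; camera adjusted p = 0.97). GstD1 rose 1.88-fold (log2 change 0.91, SE 0.06), GstE6 1.48-fold and GstD5 as given above, while Cyp4d20 fell 3.78-fold (log2 change -1.92, SE 0.20) and Cyp12d1-d 2.79-fold (log2 change -1.48, SE 0.09). Of 7 heat shock genes 1 rose, Hsp26, a small heat shock protein gene, 1.99-fold (log2 change 0.99, SE 0.12), while Hsp68 had a value of 0.45 (SE 0.18) that did not pass (camera adjusted p = 0.22 for the list). Of 19 pausing and elongation factors 1 rose, Ssrp, a subunit of the histone chaperone FACT, by 0.26 on the log2 scale (SE 0.06, camera adjusted p = 0.41 for the list). Counts over each of these latter 2 lists alone were the same.

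Few signalling genes changed. Of 16 ecdysone response genes 3 fell (3 over the list alone, with 1 rise there; camera adjusted p = 0.20): ImpE3 4.12-fold (log2 change -2.04, SE 0.20), the transcription factor gene br 2.99-fold (log2 change -1.58, SE 0.26, its 4 dimmer probe sets not passing) and Eip63E by 0.30 on the log2 scale (SE 0.07). Of 8 genes listed as Notch targets 1 fell, numb, which is known as an inhibitor of Notch rather than an E(spl) gene, 2.06-fold (log2 change -1.04, SE 0.11; 3 fell over the list alone; camera adjusted p = 0.15). The EGFR ligand gene grk fell 1.62-fold, the only change among 17 EGFR and Ras/MAPK genes (camera adjusted p = 0.97), and egr, the tumour necrosis factor ligand, 1.64-fold, the only change among 12 JNK and apoptosis genes (camera adjusted p = 0.98), with the same counts over each list alone. None of 7 JAK/STAT and Turandot genes passed (1 fell over the list alone; camera adjusted p = 0.60).

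Growth and housekeeping lists moved little. Of 28 mitosis genes 3 rose, glu, a condensin subunit, by 0.45, scra, which encodes anillin, by 0.30 and the kinase gene aurB by 0.30 on the log2 scale (4 over the list alone; camera adjusted p = 0.46). Of 28 DNA replication genes RPA1 rose by 0.26 and CycE fell by 0.31 on the log2 scale (3 rises and 2 falls over the list alone; camera adjusted p = 0.97). The calls of CycE, RPA1, aurB, scra, cher and SPARC were lost under most ways of leaving out 1 array, that of glu under 4 of 9, and against untreated cells CycE (adjusted p = 0.90) and aurB (adjusted p = 0.58) did not pass. Neither did RPA1 and glu. Of 14 glycolysis and hypoxia genes 2 fell, Hph, the prolyl hydroxylase of the hypoxia response, by 0.42 and the growth factor gene bnl by 0.62 on the log2 scale, while the other, dimmer probe set of Hph changed by -0.04 and did not pass (adjusted p = 0.98). Against untreated cells bnl did not pass. For this list 5 fell adjusted over the list alone (camera adjusted p = 0.15). Single rises were eIF6 among 22 ribosome biogenesis genes (log2 change 0.42, SE 0.07; 2 over the list alone; camera adjusted p = 0.46), Prosalpha6 among 34 proteasome subunits (log2 change 0.31, SE 0.06; 1 over the list alone; camera adjusted p = 0.055) and SdhB among 67 respiratory chain genes (log2 change 0.36, SE 0.07; 1 over the list alone; camera adjusted p = 0.43). Prosalpha6 and SdhB did not pass against untreated cells.

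No member passed among 38 cytosolic ribosomal protein genes (camera adjusted p = 0.90), 21 genes of RNA interference (0.98), 18 of endoplasmic reticulum stress (0.96), 9 germline markers (0.54) and 6 reference genes (0.91), either over all probe sets or over each list alone. The 8 neuron markers and 6 muscle and fat body markers also had no call, and too few were measured on all arrays for camera. Of 3 linker and variant histones none passed over all probe sets and 1 rose over the list alone, and the replication-dependent histones had no measured gene. Among the reference genes Gapdh1 averaged 10.74 after LacZ dsRNA and 10.78 after NELF dsRNA, and RpL32 13.09 and 13.07. Median and mean log2 change differed in sign for the JAK/STAT list (-0.02 and 0.17), the JNK list (0.01 and -0.03) and, with 1 or both values within 0.01 of 0, the extracellular matrix, DNA replication and heat shock lists.

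NELF dsRNA against untreated cells changed many of the same genes. Nelf-E fell as given above, CG44251 was at least 6.28-fold lower, Sfxn1-3 was at least 7.56-fold lower and eater fell by 2.91 (SE 0.40) on the log2 scale. CG10359 was at least 3.35-fold lower, with values on 2 NELF dsRNA arrays, both below the limit. The rises chosen by size were bbg (at least 6.50-fold), net (at least 5.12-fold), Obp44a (at least 4.57-fold) and Prx6c, a peroxiredoxin (at least 3.98-fold), each with an untreated mean below the limit, and CG9008 (3.99-fold). Prx6c did not pass against LacZ dsRNA (adjusted p = 0.092), and its call here was lost with a floor at the 10th percentile. Antimicrobial peptide genes were again lower, 4 of 5 falling (5 over the list alone), with CecB at -1.53 (SE 0.14), DptB at -1.45 (SE 0.18) and AttD at -0.71 (SE 0.13) on the log2 scale, the last lost without the variance trend or with a floor at the 10th percentile (camera adjusted p = 0.00035 for the list; adjusted p = 0.52 with an estimated correlation). Of 22 immune recognition and signalling genes 4 fell, among them pirk at -1.23 and Tl at -0.85 (6 over the list alone; camera adjusted p = 0.024; adjusted p = 0.43 with an estimated correlation), and that call was lost with the mean over all probe sets of a gene. Cytosolic ribosomal protein genes had a median log2 change of -0.09, with 35 of 38 values below 0 and none passing singly over all probe sets or over the list alone (camera adjusted p = 0.0097; adjusted p = 0.88 with an estimated correlation), and that call was lost under quantile normalization. None of the other 22 lists tested passed camera.

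Against untreated cells 799 of 12973 probe sets passed the limma test, 341 higher and 458 lower, and 356 without the variance trend. Of the 591 probe sets changed in NELF dsRNA against LacZ dsRNA and tested in both comparisons, 454 also changed against untreated cells in the same direction, 162 higher and 292 lower, and none in opposite directions. Both comparisons use the same NELF dsRNA arrays. In 20 simulations with no effect 0 probe sets passed in both, a value that decides nothing, since the test made 0 calls where nothing was changed. Independent lists of these sizes would share 6.62 higher and 13.2 lower, a figure that leaves the shared arrays out of account. The log2 changes of the comparisons had a correlation of 0.56 (0.50 in 20 simulations with no effect) and a covariance of 0.34 (0.22 simulated, a difference of 0.12) across probe sets, which are not independent replicates. With 3 arrays the shared group could not be split, so part of the overlap may come from the shared arrays.

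In LacZ dsRNA against untreated cells few genes passed the test. CG32576 rose 2.83-fold (SE 0.13 on the log2 scale, limma adjusted p = 9.0e-05) and stood at a like level after NELF dsRNA, with means of 5.67 ± 0.08 in untreated cells, 7.17 ± 0.06 after LacZ dsRNA and 7.28 ± 0.12 after NELF dsRNA (SD, n = 3). SpdS, the spermidine synthase gene, rose by 0.91 on the log2 scale, stc by 0.70, Akt, a kinase of insulin signalling, by 0.57 and schlank, a ceramide synthase gene, by 0.53. Sgt, a co-chaperone gene, fell by 0.41. After NELF dsRNA schlank and Sgt differed from LacZ dsRNA by -0.43 and 0.39 and did not pass against untreated cells. Both of these differences from LacZ dsRNA were lost without the variance trend. CG5913, named here after its values were seen, rose by 0.49. A floor at the 10th percentile ended the calls of SpdS, stc, Akt, schlank and Sgt against untreated cells. An offset at the 25th percentile ended those of SpdS, Akt and Sgt. The calls of SpdS, Akt, schlank and Sgt were lost when any of several single arrays was left out. Without the variance trend only CG32576 passed against untreated cells.

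These were the 7 probe sets past the limma test among 12974, 6 higher and 1 lower, and 1355 had an unadjusted p under 0.05. That is a larger share than 0.05 of those tested, so few calls need not mean few changes. The count was 18 without LacZ dsRNA array 1 and 22 without LacZ dsRNA array 1 and NELF dsRNA array 3, 3 without untreated array 2, untreated array 3 or LacZ dsRNA array 2, and 2 without LacZ dsRNA array 3. Cytosolic ribosomal protein genes stood lower as a list, with a median log2 change of -0.08 and 33 of 39 values below 0 (camera adjusted p = 0.0079; adjusted p = 0.85 with an estimated correlation), and that call was lost under quantile normalization and without LacZ dsRNA array 1 and NELF dsRNA array 3. The antimicrobial peptide list had a median of -0.29 with no gene passing (camera adjusted p = 0.13; adjusted p = 0.0047 without those 2 arrays, where 6 lists were called). None of those 6 passed with an estimated correlation (adjusted p = 0.50 with an estimated correlation for antimicrobial peptides, and adjusted p = 0.81 with an estimated correlation for each of the others). Of the probe sets changed in NELF dsRNA against LacZ dsRNA, none changed in the same direction here and 2 changed in opposite directions, where the LacZ dsRNA arrays enter with opposite signs (correlation of changes -0.43, simulated -0.50; covariance -0.24, simulated -0.22).

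Against all 6 control arrays together, NELF-B fell by 2.66 (SE 0.14, limma adjusted p = 5.0e-09) on the log2 scale after NELF dsRNA. The genes eater and CecB fell by 2.78 (SE 0.34) and 1.32 (SE 0.15), while oaf and GstD1 rose by 1.36 (SE 0.08) and 0.95 (SE 0.05). This comparison gave 743 changed probe sets of 13990 tested by limma, 306 higher and 437 lower. With a change of at least 1.5-fold as well, 110 were higher and 275 lower, and without the variance trend 363 probe sets passed.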

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

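The tests of array scaling and of the share of falls without each array or with 1 probe set per gene were chosen only after the result was seen. So was the comparison of list means for dsRNA as such, and so was leaving out LacZ dsRNA array 1 and NELF dsRNA array 3.

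A second probe set for Timp had too few values for a test against LacZ dsRNA but stood above the detection limit on the 3 NELF dsRNA arrays, with a mean of 4.69 there and 1 value among the LacZ dsRNA arrays. Against untreated cells, with 2 values, this Timp probe set passed (limma adjusted p = 0.022). A probe set for Spn28Dc, a serpin gene, averaged 4.62 on the 3 LacZ dsRNA arrays, above the limit on each, with 1 value among the NELF dsRNA arrays.

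Among probe sets changed by at least 1.5-fold in NELF dsRNA against LacZ dsRNA, 72.0% were falls. The share was 71.1% under quantile normalization or median scaling, whichever was lower. This argues against uneven scaling left in the deposited values as the whole cause. The largest shift of an array under these methods was 0.084 and 0.016 on the log2 scale, so they could change little. Scaling done before deposit could not be tested. Dim values near the floor are argued against as well, since falls made up 71.3% of the 293 such probe sets with both group means above the detection limit, 66.8% to 72.1% without each array in turn and 76.4% with 1 probe set per gene (probe sets are not independent, so no interval is given). A candidate explanation that stays open, as a hypothesis, is an effect of NELF depletion. An effect of the dsRNA mixture on other messages was not tested, because 1 mixture was used.

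In NELF dsRNA against LacZ dsRNA 2 of 5 antimicrobial peptide genes fell, and the list's camera call (adjusted p = 0.0033) was lost with an estimated correlation (adjusted p = 0.46 with an estimated correlation). The list mean was lower by 0.69 on the log2 scale than after LacZ dsRNA (-0.69), and lower on each NELF dsRNA array than on any LacZ dsRNA array. Both groups received dsRNA, so by design its presence alone cannot be the whole cause of this difference. The values come from the arrays that gave the result and are no separate support. A contribution of dsRNA stays open: LacZ dsRNA minus untreated was -0.23, and without LacZ dsRNA array 1 and NELF dsRNA array 3 the list passed camera in that comparison (adjusted p = 0.0047; adjusted p = 0.50 with an estimated correlation, a call lost). How much a state shared by those 2 arrays adds to the size of the fall stays open: without them the median moved from -0.55 to -0.28 and did not stay below -0.3, the bound written before that value was seen, while the mean of the list moved less, from -0.69 to -0.54, and on the list mean LacZ dsRNA array 1 stood apart (7.97 against 7.51 and 7.52) but NELF dsRNA array 3 (6.99) lay between the other NELF dsRNA arrays (6.91 and 7.05). No biological explanation of the fall, NELF depletion included, was tested.

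For 3 arrays against 3, the 10 splits are too few for a share under 0.05. As many probe sets as the real split's 592 changed in 1 of 10 splits for NELF dsRNA against LacZ dsRNA (highest other split 1), as many as 799 in 1 of 10 against untreated cells (highest other 0), and as many as 7 in 1 of 10 for LacZ dsRNA against untreated cells (highest other 2). For NELF dsRNA against all 6 controls, 1 of 84 splits, the real one, gave as many as 743 probe sets, and the highest other gave 5. That share is under 0.05 and makes a chance split of the arrays unlikely there. These splits treat untreated and LacZ dsRNA arrays as alike, and they cannot address a culture or batch difference that goes with the group.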

How the results depend on the processing

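Only the settings without LacZ dsRNA array 1 and NELF dsRNA array 3, and with only probe sets measured on all 9 arrays, were chosen after seeing the data. Without the variance trend the counts of changed probe sets were 228 for NELF dsRNA against LacZ dsRNA, 356 against untreated cells, 363 against all 6 controls and 1 for LacZ dsRNA against untreated cells. With a fold of at least 1.5 as well they were 325, 413, 385 and 3, fewer by construction. LacZ dsRNA against untreated cells also gave 3 with the offset at the 25th percentile, 12 with 1 probe set per gene and 22 without LacZ dsRNA array 1 and NELF dsRNA array 3. Leaving out each array in turn, counts ranged from 426 to 697, from 534 to 996, from 505 to 872 and from 2 to 18, in the same order. With the replicate number as a block the counts were 531, 724, 678 and 9. The numbers gave no clear pairing of the arrays. Deviations from group means had correlations from -0.21 to 0.13 between same-numbered arrays and up to 0.25 between others. For 5 of the 9 arrays the best partner had the same number. Lists called by camera went from 1 to 0 with an estimated correlation for NELF dsRNA against LacZ dsRNA, from 3 to 0 against untreated cells and from 1 to 0 for LacZ dsRNA against untreated cells, where quantile normalization also gave 0. Without those 2 arrays they numbered 3 for NELF dsRNA against LacZ dsRNA and 6 for LacZ dsRNA against untreated cells. Where no construction shows it, the cause was not tested. Against LacZ dsRNA, NELF-B ranged from -2.85 to -2.71 and Nelf-E (fitted, its NELF dsRNA mean below the limit) from -4.67 to -4.02 without 1 array, passing each time, and since each has 1 probe set the mean over all probe sets of a gene could not be tried for them. The named genes gave 125 called values. Each was counted once under every alternative it could be tried with, which gave 1812 calls kept, 295 lost and 0 turned in direction. Without the variance trend 57 of the 125 lost their call, and with a floor at the 10th percentile 44 did. Values near the detection limit of 3.77 bound what the dim probe sets can show.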

Other observations

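Every gene group and test here was chosen only after the result was seen. Called genes with a mean log2 value above 5 had been listed before the groups were written, so counts over a whole group lean towards change and tests on its remaining members lean towards none.

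After NELF dsRNA against LacZ dsRNA, 7 of 27 lysosomal hydrolases and transporters fell and 1 rose, among them Naglu (log2 change -1.31), Sgsh (-1.28) and Ids (-1.26), enzymes that break down glycosaminoglycans, and Npc2b (-1.36). Of 36 genes of DNA damage response and repair 6 rose, among them Ku80 (0.86), Irbp (0.63), Xpc (0.45) and mre11 (0.41). Of 22 genes of glutathione synthesis and oxidative stress defence 9 rose, among them Gclc (0.39), Gtpx (0.34) and Mrp4 (0.44). These 9 include GstD1, GstD5 and GstE6, which are also counted among the detoxification genes above and below.

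A hypothesis for each is that the group may move as a whole and not only in the members that prompted it. The members not seen before gave a limma camera adjusted p = 0.55 for the lysosomal group (19 tested, median -0.07), adjusted p = 0.19 for DNA repair (30 tested, median 0.07) and adjusted p = 0.59 for glutathione synthesis and defence (13 tested, median 0.06). These tests were built from members without a call, so they leave the hypotheses open.

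Among detoxification genes the direction may go with the enzyme family. Of 30 glutathione S-transferases 7 rose and 3 fell, and of 50 cytochromes P450 1 rose and 8 fell (exact two-sided Fisher test of family against direction, p = 0.020). Genes of a family are not independent replicates, and the pattern was found in the same data.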
